A study of Mus musculus with 36 samples.

How the data were processed

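Gene expression was measured on Affymetrix MG_U74Av2 arrays in 5 muscles (diaphragm, extensor digitorum longus, gastrocnemius, plantaris and tibialis anterior) of wild-type mice and of mice transgenic for alpha tropomyosin slow, at 7 and 10 months of age. Per the labels each of the 36 arrays was hybridized with RNA pooled from 3 to 5 mice, 8 micrograms of total RNA being labelled. Diaphragm, gastrocnemius and tibialis anterior had 4 arrays per genotype, and extensor digitorum longus and plantaris 3, with 1 array per genotype at 10 months. Of the 20 groups of muscle, genotype and age, 16 had 2 arrays and 4 had 1. The mouse strain and the form of the transgene are not given in the sources used here, and sex is given for 1 array.

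The deposited values are MAS5 signal intensities, per the submitters' processing notes, from 0.1 to 257806.6 and not log-transformed. The MAS5 version and its settings are not given in the sources used here. The trimmed mean of each deposited array lay between 1500.93 and 1501.29, so the authors had scaled the arrays to a shared target. All 36 deposited columns were assigned to a sample, and 0 columns of other samples were found. Between 57.4 and 68.4% of probe sets reached a scaled signal of 100 (median 62.55%). Correlations within groups lay between 0.847 and 0.941, the highest of all pairs was 0.972, and 0 pairs were identical. The 3' to 5' ratio of Gapdh was 3.32 and 3.69 on 2 arrays, one of gastrocnemius and one of plantaris, and at most 1.80 on the others. Arrays have no read depth, and the number of arrays and the spread between them limit the precision of each comparison.

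Each array was scaled to a 2% trimmed mean of 500, and log2(signal + 50) was used. Of 12488 probe sets 66 controls were left out. The 9322 probe sets that reached 100 on at least 6 of the 36 arrays were tested. Gene symbols came from the array's annotation, and 10817 of the 10833 probe sets with 1 symbol were matched to the reference table by gene ID. Of those tested 8308 had 1 symbol, 314 several and 700 none, for 6793 genes. Comparisons were made in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a linear model of muscle by genotype and an age effect for each muscle, and an intensity trend in the moderated variance. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The comparisons were genotype in each muscle, genotype averaged over the 5 muscles, the difference of the genotype effect between muscles (moderated F test) and between the diaphragm and the mean of the 4 limb muscles. Differences between wild-type muscles were compared in the same way, at the 7-month level of the model, whose age effect for each muscle is shared by both genotypes. Where the signal of a group lies under 100, the size of a change depends on the pseudocount. Age in each genotype and the interaction came from a model with 20 means, for each muscle, genotype and age. Values are given as log2 change ± SE, and signals as mean ± SD over arrays.

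Gene lists were tested with camera at the preset correlation of 0.01, with camera at an estimated correlation, and with fry, using 1 probe set per gene and adjustment over 20 lists. The 21 lists were slow and fast fibre sarcomere and calcium handling, myogenic regulators and developmental genes, denervation and atrophy, Z-disc and thin filament, extracellular matrix, macrophage and myeloid, lymphocyte, endothelial, adipocyte, nerve and Schwann cell and erythroid markers, oxidative phosphorylation, glycolysis and glycogen, fatty acid uptake and oxidation, heat shock and unfolded protein, cell cycle, proteasome, immediate early, circadian clock and sex-linked genes. Only Xist of the sex-linked list was tested. A hepatocyte list of 21 tested genes was added after the data were seen, outside the adjustment over lists. Numbers of members past the threshold over all probe sets are given beside numbers adjusted over the list alone.

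A gene was represented by its probe set with the highest mean signal. Named genes followed a rule. Tropomyosin genes were named everywhere. For the average these were joined by the 12 largest rises and 12 largest falls past the threshold that moved the same way in all 5 muscles. For each muscle the 6 largest rises and falls past the threshold without overlap between genotypes were named. For the other comparisons these were the 6 largest in each direction, or the 10 smallest p in F tests. For lists up to 4 members past the threshold with the largest change were named, or else those with the highest signal. Genes outside the rule are marked as chosen after their values were seen.

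Each group of 2 arrays carries replicate numbers 1 and 2. They were to be taken as pairs only where deviations within groups correlated over 0.1 in every pair of groups. They did in 117 of 120 (lowest 0.0066, median 0.33, highest 0.7), so the block is not in the model but is given beside it. Arrays with the same number share some factor, and whether that is a batch or shared pools of mice was not tested. Replicate 1 (20 arrays) coincides with a filled experiment record and replicate 2 (16 arrays) with an empty one. In all 3997 probe sets differed between the replicate numbers (1738 higher and 2259 lower in replicate 2), so values with this set as a block and within each set are given beside results that they change. The models with and without this block were run at the same time. The filled-record arrays had 9 scan days. Wild-type and transgenic arrays of the same muscle and age were scanned on different days in 9 of 10 pairs, so on these arrays the genotype is not separated from the scan day within a pair. The empty-record arrays have no scan day.

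Alternatives tried were the set of arrays or scan day as a block, each set alone, a random block for possible shared pools, array weights, each muscle alone, the 20 group means, quantile normalization, the deposited values with no rescaling (under which a pseudocount of 50 and a floor of 100 are smaller beside the signal, and 11708 probe sets are tested), 1 probe set per gene, pseudocounts of 16 and 200, no filter and a stricter filter at a mean signal of 200, and leaving out each array in turn. Added after the data were seen were wild-type muscles with the ages weighted equally, a hepatocyte covariate in the diaphragm, the 4 limb muscles alone, each also with the block, leaving out the 2 arrays with a high Gapdh ratio, leaving out a gastrocnemius array whose record names plantaris, and list tests with an estimated correlation plus the block or the covariate. Labels of the arrays were also split at random, keeping group sizes, up to 100 times. In single muscles with 4 arrays per genotype 34 of the 35 possible splits were used, since the split by age cannot be fitted, and in the others all 10, and the called probe sets were counted. The splits for diaphragm and for age in wild type were also counted with the block, after the data were seen.

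The model was tested on simulated data with 9322 probe sets of which 200 changed. A log2 change of 1 was recovered for 46, 31, 50, 28 and 48% in diaphragm, extensor digitorum longus, gastrocnemius, plantaris and tibialis anterior, and for 91% in the average. A log2 change of 2 was recovered for 91 to 96% in single muscles and 100% in the average. For the F test between muscles these were 9 and 84%, for the diaphragm against the limb muscles 32 and 90%, for age 72 and 99% (wild type) and 75 and 98% (transgenic), for the interaction 42 and 96%, and for wild-type muscles 14 and 88%. False calls were 2.1 to 9.4% of all calls. A simulated list shifted by 0.5 was called with both correlations, and 0 of the unshifted lists were. The simulated noise was independent between genes and held no effect of the replicate number. The rates on the real arrays may therefore differ, and the simulation cannot compare the 2 correlations.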

Results

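Averaged over the 5 muscles, transgenic arrays carried more RNA for Ankrd2 and Csrp3, whose products sit at the sarcomere and in the nucleus and take part in the response of muscle to stretch. Xirp1, Enah and Nrap, which help to build and repair thin filaments and their attachments, and Pdlim1, an adaptor that anchors actin at the Z-disc, also rose. So did slow fibre genes, with the largest log2 changes in tibialis anterior. These were Myl2 and Myh7 for the slow myosin chains, Tnni1 for slow troponin I and Atp2a2 for the calcium pump of slow fibres. Bag3, a co-chaperone that helps to clear damaged filament proteins, rose as well, and Ak4, a mitochondrial adenylate kinase, fell. Ankrd2 showed a log2 change of 2.32 ± 0.13 (estimate ± SE; signal 1540 ± 1030 in wild-type and 7510 ± 2790 in transgenic arrays, mean ± SD, n = 18 each; adjusted p = 2.4e-12). Csrp3 followed at 1.78 ± 0.17 (adjusted p = 1.2e-07), Xirp1 at 1.18 ± 0.15 (adjusted p = 2e-05), Pdlim1 at 1.02 ± 0.13 (adjusted p = 1.5e-05; a second Pdlim1 probe set had -0.32) and Enah at 0.89 ± 0.14 (adjusted p = 0.00047). For each of these 5 genes all 18 transgenic arrays lay above the wild-type mean of their muscle. The slow fibre genes had changes of 0.91 (Myl2, adjusted p = 2.7e-05), 0.87 (Myh7, adjusted p = 0.0079), 0.81 (Tnni1, adjusted p = 0.00042) and 0.74 (Atp2a2, adjusted p = 0.0015), in the same direction on 15, 15, 17 and 17 of the 18 transgenic arrays. In tibialis anterior they had 3.21, 3.24, 1.57 and 1.54, and in the other muscles 0.01 to 0.76, 0.07 to 0.46, 0.46 to 0.71 and 0.30 to 0.91. The test of the difference between muscles passed for Myl2 and Myh7, and not for Tnni1 or Atp2a2. This ranking and test are on the log2 scale, and wild-type tibialis anterior had the lowest Myl2 and Myh7 signal. In signal Tnni1 gained 1620 and Atp2a2 478 in tibialis anterior. Their means over the 18 arrays of each genotype went from 7610 to 12000 and from 3400 to 4790.

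**Figure D1:**
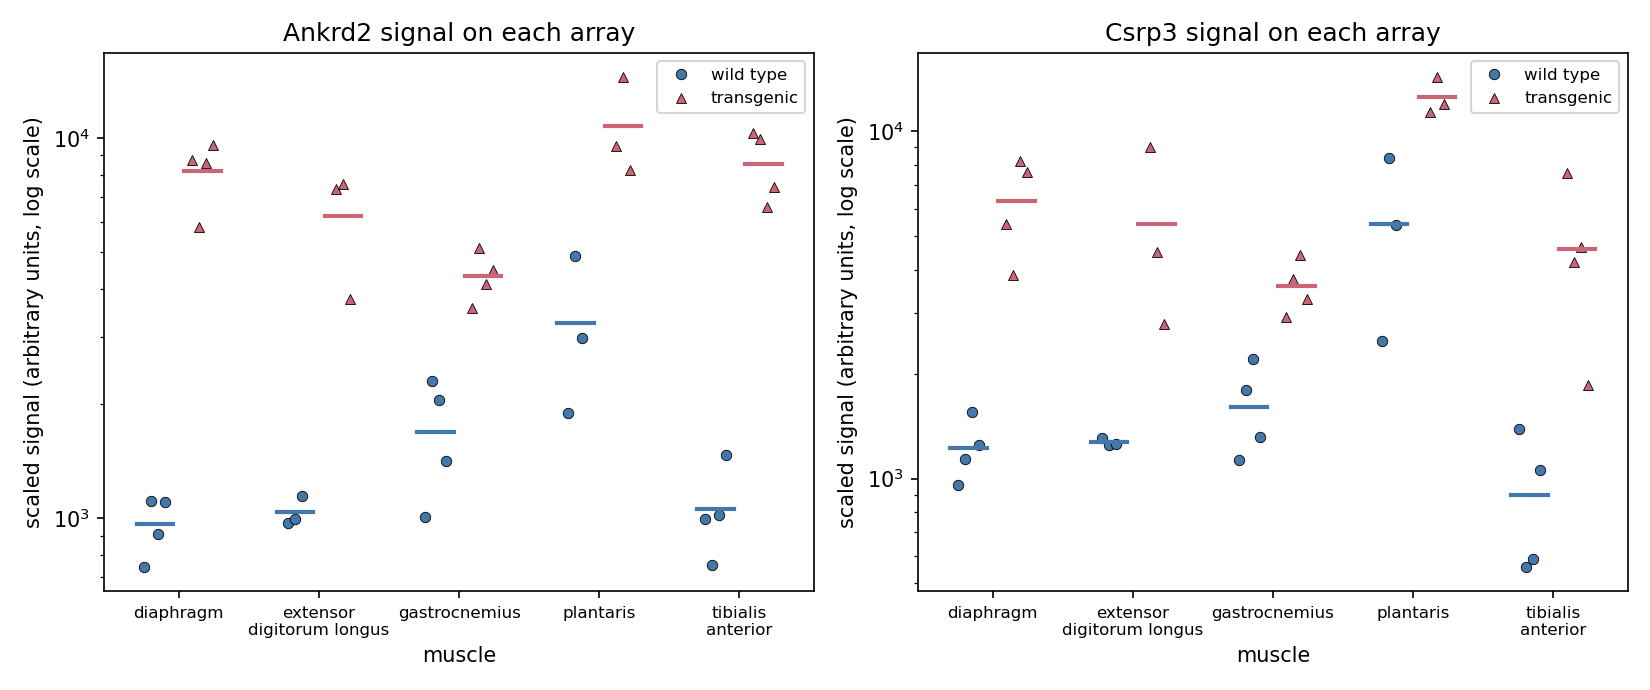
Scaled signal of Ankrd2 and Csrp3 on each array, by muscle and genotype, with bars at the means. Their log2 changes averaged over the 5 muscles were 2.32 and 1.78.

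The other large rises were St3gal5, which makes the ganglioside GM3 (0.92, adjusted p = 0.00042, 16 of 18 arrays), and Padi2, which converts arginine to citrulline in proteins (0.87, adjusted p = 5e-05, 17 of 18). Nrap had 0.85 (adjusted p = 1.5e-05, 18 of 18), Mast2, a microtubule-associated kinase, 0.84 (adjusted p = 0.045, 18 of 18) and Rcan1, an inhibitor of calcineurin, 0.82 (adjusted p = 4.1e-05, 17 of 18). Bag3 rose by 0.70 ± 0.07 (adjusted p = 1.7e-06, 18 of 18). Ak4 changed by -0.81 ± 0.09 (signal 574 ± 281 to 310 ± 140; adjusted p = 4.3e-06) and Gp5, known as a platelet glycoprotein, by -0.75 (adjusted p = 0.0012), both lower on all 18 transgenic arrays. The 12 largest falls were taken among genes lower in all 5 muscles, by the probe set of each gene with the highest mean signal. The other 10 were Klf17, a zinc finger factor (-0.66, adjusted p = 0.0054), Nr1i3, a nuclear receptor (-0.66, adjusted p = 0.0091), and Nat8f1, Zbtb37, Grin2d, Plxna1, Slc6a13, Nt5e, Hif3a and Celf4, with changes between -0.71 and -0.54. Mean signals over all arrays lay near the floor of 100 for Gp5 (91.6), Celf4 (100.6), Nt5e (117.3), Grin2d (120.2) and Zbtb37 (124.2). The sizes of these falls therefore depend on the pseudocount. For the other falls the mean signals were 201.3 (Plxna1) to 700.1 (Nr1i3). In all, 109 of 9322 probe sets passed the threshold (80 higher and 29 lower; limma, Benjamini-Hochberg adjusted p under 0.05). Of these 99 had a single gene symbol, for 94 genes. For 87 genes the probe set with the highest mean signal passed, and 78 of these moved the same way in all 5 muscles. At unadjusted p under 0.05 there were 1613. With the set of arrays (replicate number) as a block the count was 594 (331 higher and 263 lower), and all 109 were among them. With a random block for muscles that may share pools of mice it was 20 (19 higher and 1 lower), with array weights 444, with 20 group means 67 and with scan day as a block 973 (433 higher and 540 lower, 100 shared). On the filled-record arrays wild type and transgenic were scanned on different days in 9 of 10 pairs of muscle and age, so there the genotype is not separated from the scan day within a pair. Within the arrays with a filled experiment record 56 passed, 32 of them shared, and within those with an empty one 2 passed. The log2 change in these sets was 2.36 and 2.30 for Ankrd2 and 1.96 and 1.53 for Csrp3. The count was 66 without either 10-month extensor digitorum longus array, wild type or transgenic, 71 without plantaris wild type 7 months replicate 2 and 72 without plantaris transgenic 7 months replicate 1. It was 190 without diaphragm wild type 10 months replicate 1, 269 without diaphragm transgenic 7 months replicate 2 and 252 without tibialis anterior wild type 10 months replicate 1. Nes, Psmb1, Mast2 and the falls of Nat8f1, Zbtb37, Grin2d, Plxna1, Slc6a13, Nt5e, Hif3a and Celf4 each lost the threshold without any of several single arrays, from 3 of them for Celf4 to 25 for Mast2 and Nes. The highest adjusted p was 0.12, for Grin2d and Nt5e without extensor digitorum longus wild type 10 months. For the other 6 of these falls it was between 0.066 and 0.11 without the same array. For Mast2 it was 0.11 without extensor digitorum longus transgenic 10 months, and for Nes 0.092 and Psmb1 0.088 without plantaris transgenic 7 months replicate 2. With the hepatocyte signal of the diaphragm arrays as a covariate 48 passed (40 higher and 8 lower), and without the 2 arrays with a high Gapdh ratio 67. In the 4 limb muscles alone 37 probe sets passed, with Ankrd2 at 2.15, Csrp3 at 1.66 and Xirp1 at 1.01. The p-values measure only the spread between these arrays, which may be technical, since nothing in the sources used here says that replicate arrays came from separate pools of mice.

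Among the gene lists fixed before the data were examined, the slow fibre list, which holds the sarcomere and calcium-handling genes of slow muscle, shifted up on average over the muscles. The Z-disc and thin filament list, whose products anchor actin, and the proteasome list, whose products degrade tagged proteins, shifted up too. Of 10 slow fibre genes 5 rose (9 adjusted over the list alone, median log2 change 0.70, camera adjusted p = 2.2e-12). With an estimated correlation the adjusted p = 0.0067, and with the block as well the adjusted p = 0.034. Of 17 Z-disc genes 3 rose (7 adjusted over the list alone, median 0.21, adjusted p = 2.5e-06; adjusted p = 0.014 with an estimated correlation and adjusted p = 0.071 when the block was added). Of 28 proteasome genes 3 rose (15 adjusted over the list alone, median 0.22, adjusted p = 2.7e-11; adjusted p = 0.048 with an estimated correlation and adjusted p = 0.071 when the block was added). These were Psmd7 and Psmd4, caps of the 26S particle (0.40, adjusted p = 0.0079, and 0.38, adjusted p = 0.0071), and the core subunit Psmb1 (0.37, adjusted p = 0.039).

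The heat shock and unfolded protein list, whose products refold proteins, passed with the preset correlation (2 of 19 rose, Bag3 and the small heat shock protein Hspb8 at 0.36; 5 adjusted over the list alone, median 0.27, adjusted p = 1.3e-05). With an estimated correlation its adjusted p = 0.1. Its median was 0.02 in the arrays with a filled record (adjusted p = 0.22) and 0.41 in the others (adjusted p = 4.4e-09). The extracellular matrix list (0 of 22 past the threshold; 0 adjusted over the list alone, median 0.19, adjusted p = 0.017) had adjusted p = 0.07 with an estimated correlation. The fatty acid list (0 of 18; 1 rose adjusted over the list alone, median 0.15, adjusted p = 0.02) had adjusted p = 0.4 with an estimated correlation. At the preset correlation 6 of 20 lists passed, all of them up, and with the set of arrays as a block 7 did (6 up and 1 down). The lists not named above did not pass without the block. Their medians were -0.10 for fast fibre genes (adjusted p = 0.081), 0.05 for myogenic regulators (adjusted p = 0.058), 0.03 for oxidative phosphorylation (adjusted p = 0.23) and -0.04 for glycolysis (adjusted p = 0.49). In the myogenic list 2 of 20 rose (2 adjusted over the list alone), namely Myf6, a myogenic transcription factor (0.59, adjusted p = 0.0096), and Nes, an intermediate filament of young fibres (0.40, adjusted p = 0.045). In the denervation and atrophy list 2 of 16 rose (2 rose and 1 fell adjusted over the list alone), namely Eif4ebp1, a brake on translation (0.46, adjusted p = 0.0041), and Bnip3, which acts in mitochondrial autophagy (0.42, adjusted p = 0.0034). That list's median was -0.03 although its test pointed up (adjusted p = 0.48). The macrophage list had a median of -0.07 (adjusted p = 0.23), the lymphocyte list -0.27 (adjusted p = 0.098), the endothelial list 0.03 (adjusted p = 0.48) and the adipocyte list 0.03 (adjusted p = 0.55). Nerve and Schwann cell markers had -0.12 (adjusted p = 0.5), erythroid markers -0.35 (adjusted p = 0.076), cell cycle genes -0.13 (adjusted p = 0.076), immediate early genes -0.09 (adjusted p = 0.24) and clock genes -0.08 (adjusted p = 0.56). Among the sex-linked genes only Xist, which silences an X chromosome, was tested (-0.19 ± 0.19, adjusted p = 0.63).

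**Figure D2:**
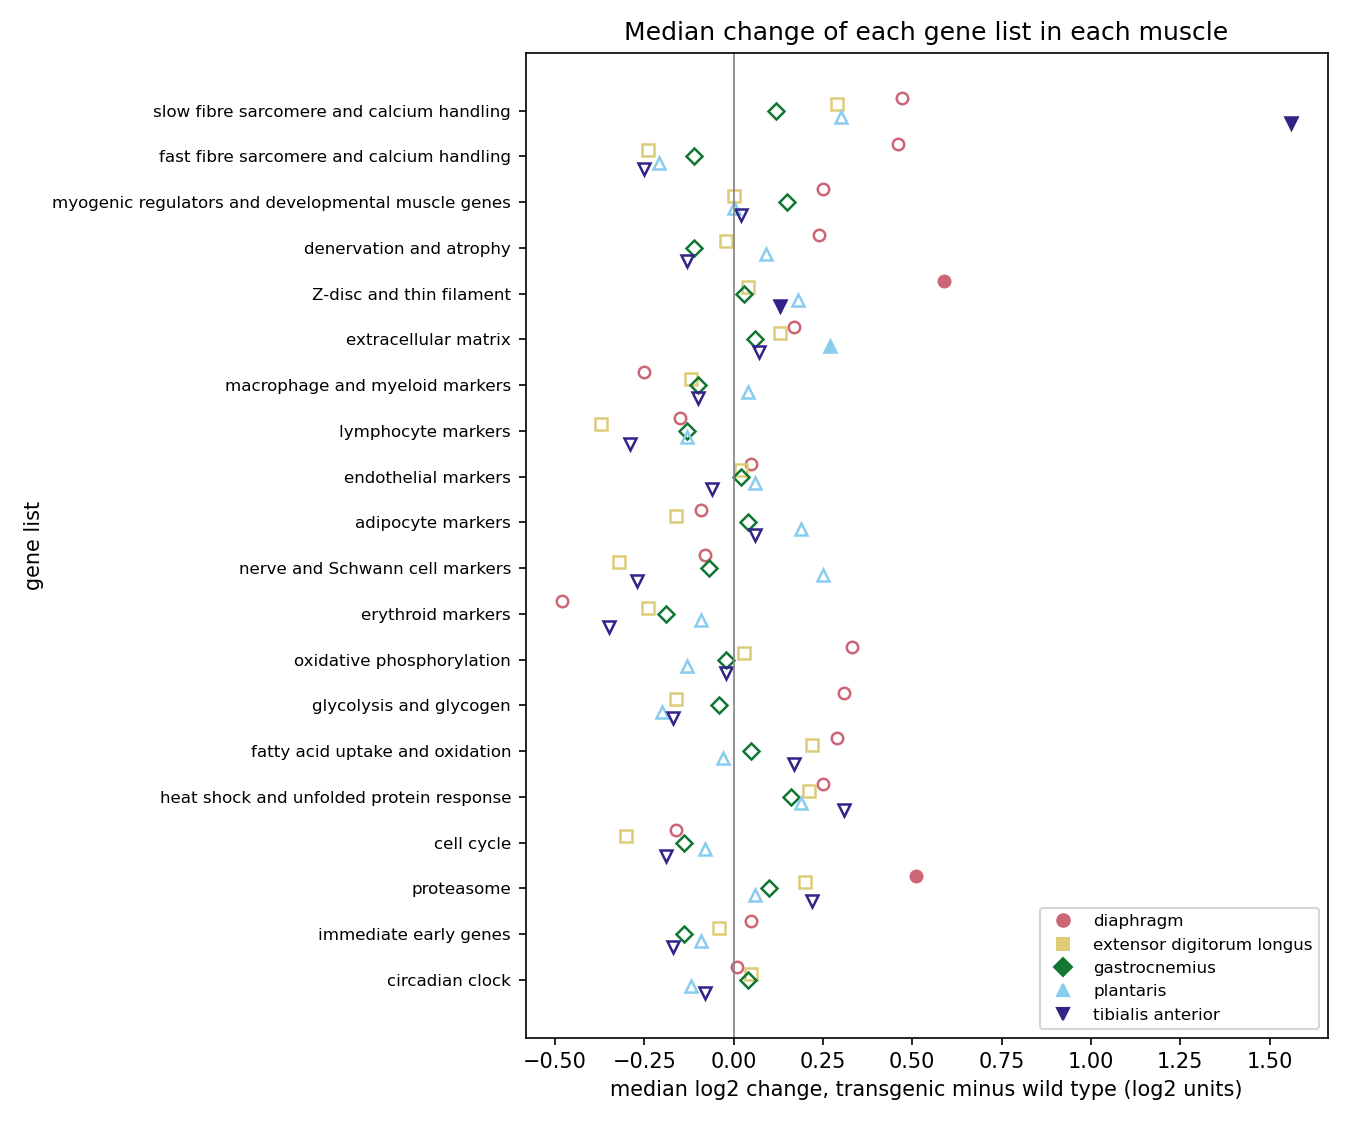
Median log2 change of each gene list in each muscle, filled where the adjusted p was under 0.05 with both the preset and an estimated correlation. The slow fibre list had a median of 1.56 in tibialis anterior and the Z-disc list 0.59 in diaphragm.

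Some genes with related functions also passed on average, and these were chosen after their values were seen. Lmna, for the nuclear lamina, had a log2 change of 0.52, Sspn, a member of the dystrophin complex, 0.75, and Mapk12, a muscle p38 kinase, 0.50. Yap1, a growth regulator that responds to tension, had 0.35, its partner Amot 0.68, and Lims1, an adhesion adaptor, 0.57. Each was higher on all 18 transgenic arrays. The actin regulators Twf2 (0.78), Wdr1 (0.51) and Diaph1 (0.47) were higher on 17, 17 and 15 of them, while Cyfip2, a regulator of actin branching, fell (-0.445, adjusted p = 0.0223, lower on 15). These genes form no tested list.

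Of the tropomyosin genes, which encode the coiled coils along the thin filament, none passed on average. Tpm3, the mouse gene for alpha tropomyosin slow, had a log2 change of 0.36 ± 0.18 (signal 11700 ± 7410 to 14200 ± 8590, mean ± SD, n = 18 each; adjusted p = 0.29). Tpm2, for beta tropomyosin, had 0.28 ± 0.08 (adjusted p = 0.07, and adjusted p = 0.031 with the block). A second Tpm2 probe set had -0.6 in tibialis anterior, -0.63 in plantaris, -0.29 in extensor digitorum longus and 0.24 in gastrocnemius. Its diaphragm value is not given here. The rise of Tpm2 in the diaphragm below therefore rests on the probe set with the highest mean signal. Tpm1 had -0.15 ± 0.09 (adjusted p = 0.38) and Tpm4 -0.08 ± 0.09 (adjusted p = 0.66). The mouse Tpm3 probe set need not detect the transgene.

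In the diaphragm the transgenic arrays carried several times more Ankrd2 and Csrp3 RNA, and more of Xirp1, Nrap and Padi2. Hoxa7, a homeobox gene of axial patterning, rose from a low signal, and Tpm2 rose alongside. Of 20 myogenic regulators 3 rose, Myog and Myf6, which drive muscle differentiation, and Mef2c, their transcriptional partner. Ak4 fell, as did Cyp17a1, a steroid-making enzyme, and 17 of 21 genes that hepatocytes express. Ankrd2 changed by 3.01 ± 0.28 (signal 966 ± 175 to 8180 ± 1640, mean ± SD, n = 4 each; adjusted p = 2.3e-07) and Csrp3 by 2.27 ± 0.35 (1230 ± 251 to 6290 ± 2030; adjusted p = 0.00079). Padi2 followed with 1.87 ± 0.25 (adjusted p = 0.00018), Xirp1 with 1.86 ± 0.31 (adjusted p = 0.0017), Hoxa7 with 1.77 ± 0.36 (47.2 ± 25.2 to 276 ± 39.6; adjusted p = 0.0055) and Nrap with 1.54 ± 0.22 (adjusted p = 0.00055). The wild-type signal of Hoxa7 and the transgenic signals of Cyp17a1 (44.3 ± 15.4) and Tmem30b (80.5 ± 29.9) lay under 100, so the sizes of their changes depend on the pseudocount. With pseudocounts of 16 and 200 Hoxa7 had 2.27 and 0.95, Cyp17a1 -1.77 and -0.66 and Tmem30b -1.50 and -0.71. With 16 Tmem30b and Itln1 reached adjusted p = 0.0512, Sc5d 0.0571 and Ptprd 0.0599. With the hepatocyte signal as a covariate only Ankrd2 of the genes in this paragraph kept the threshold (2.78, adjusted p = 0.003). Csrp3 had 1.93 (adjusted p = 0.73), Padi2 1.79 (adjusted p = 0.19), Xirp1 1.72 (adjusted p = 0.89), Nrap 1.28 (adjusted p = 0.59), Hoxa7 1.58 and Tpm2 0.58 (adjusted p = 1 for both). The falls had adjusted p = 1, among them Cyp17a1 at -1.05 and Ak4 at -0.84. Tpm2 had 0.69 ± 0.17 (10100 ± 1900 to 16400 ± 2600; adjusted p = 0.016), while Tpm3 had 0.42 (adjusted p = 0.74), Tpm1 -0.24 (adjusted p = 0.71) and Tpm4 -0.06 (adjusted p = 0.95). The largest falls without overlap at a pseudocount of 50 were Cyp17a1 (-1.33, adjusted p = 0.0028), the sterol enzyme Sc5d (-1.26, adjusted p = 0.033) and the flippase subunit Tmem30b (-1.23, adjusted p = 0.028). Itln1, a lectin (-1.09, adjusted p = 0.049), Ptprd, a receptor phosphatase (-0.89, adjusted p = 0.049), and Ak4 (-0.89 ± 0.19, adjusted p = 0.0073) followed. Ankrd2, Csrp3, Padi2, Xirp1, Hoxa7, Nrap, Cyp17a1, Sc5d, Tmem30b, Itln1, Ptprd and Ak4 were named among genes without overlap between genotypes. That each of the 4 transgenic arrays lay beyond each wild-type array thus follows from the rule.

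In the diaphragm 319 probe sets passed (111 higher and 208 lower; 1179 at unadjusted p under 0.05). With the set of arrays as a block there were 536 (250 higher and 286 lower), with array weights 633, with 20 group means 204 (61 higher and 143 lower) and with scan day as a block 146 (92 higher and 54 lower). With the diaphragm arrays fitted alone 2 passed, both higher (952 at unadjusted p under 0.05). Within the filled-record arrays there were 303 (217 shared) and within the empty-record arrays 0 (limma; 479 at unadjusted p under 0.05). Ankrd2 changed by 3.32 and 2.70 and Csrp3 by 2.40 and 2.14 in these sets. The count was 102 without diaphragm wild type 7 months replicate 1, 65 without diaphragm wild type 10 months replicate 2, 67 without diaphragm transgenic 7 months replicate 1 and 135 without diaphragm transgenic 10 months replicate 1. Ankrd2, Csrp3, Padi2, Xirp1, Hoxa7, Nrap, Cyp17a1, Bag3, Psmb1, Fabp1 and Apoa1 kept the threshold without any 1 array. Others lost it, with the highest adjusted p here in brackets. Tpm2 (0.11), Sc5d (0.16) and Ptprd (0.36) had it without wild type 7 months replicate 1, Tmem30b (0.22) and Ak4 (0.073) without transgenic 7 months replicate 1 and Itln1 (0.33) without transgenic 10 months replicate 1. The arrays without which each lost it numbered 5 for Tpm2, 6 for Sc5d, 29 for Ptprd, 4 for Tmem30b, 2 for Ak4 and 30 for Itln1.

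The diaphragm's Z-disc and thin filament list shifted up, led by Ankrd2, Csrp3, Xirp1 and Pdlim3, the last an adaptor between actinin and its partners. The proteasome list shifted up too. Of 17 Z-disc genes 6 rose (8 adjusted over the list alone, median 0.59, adjusted p = 7.4e-09; adjusted p = 0.0043 with an estimated correlation, and adjusted p = 0.019 with the block added). Pdlim3 had 1.22 (adjusted p = 0.035, and adjusted p = 0.28 at highest, without diaphragm transgenic 7 months replicate 1). Of 28 proteasome genes 7 rose (14 adjusted over the list alone, median 0.51, adjusted p = 5.4e-14; adjusted p = 0.029 with an estimated correlation, and adjusted p = 0.041 with the block added). Psmb1 had 1.18 ± 0.19 (adjusted p = 0.0012), the cap subunits Psmd12 0.97 (adjusted p = 0.047), Psmd4 0.75 (adjusted p = 0.0067) and Psmd7 0.71 (adjusted p = 0.017). Psmd12 and Psmd7 reached adjusted p-values of 0.33 and 0.16 without diaphragm wild type 10 months replicate 2, and Psmd4 reached 0.074 without transgenic 7 months replicate 1. Hepatocyte genes fell on the same arrays, and with their mean signal as a covariate the proteasome list had a median of 0.22 (adjusted p = 0.26) and the Z-disc list adjusted p = 0.002, each with an estimated correlation.

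Another 8 diaphragm lists passed with the preset correlation alone. Slow fibre genes had a median of 0.47 (1 of 10 rose, Fhl1, a scaffold of the sarcomere, at 0.90; 1 adjusted over the list alone, adjusted p = 0.00045, and adjusted p = 0.15 with an estimated correlation). Fast fibre genes had 0.46 (1 of 12 rose, the Z-disc protein Myoz1 at 0.59; 5 adjusted over the list alone, adjusted p = 8.6e-05, and adjusted p = 0.27 with an estimated correlation). Myogenic regulators had 0.25 (3 of 20 rose; 4 adjusted over the list alone, adjusted p = 0.006, and adjusted p = 0.13 with an estimated correlation), with Mef2c at 1.27 (adjusted p = 0.021), Myog at 1.22 (adjusted p = 0.038) and Myf6 at 1.02 (adjusted p = 0.024). Without diaphragm transgenic 7 months replicate 1 Mef2c reached 0.18, Myf6 0.24 and Myoz1 0.16, without wild type 7 months replicate 1 Myog reached 0.29, and without wild type 10 months replicate 2 Fhl1 reached 0.058 and Hspb8 0.065 (adjusted p). Heat shock genes had 0.25 (2 of 19 rose, Bag3 at 0.97 and Hspb8 at 0.67; 3 adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.36 with an estimated correlation), with medians of -0.07 and 0.48 in the filled-record and empty-record arrays. Oxidative phosphorylation had 0.33 (0 of 40; 0 adjusted over the list alone, adjusted p = 6.7e-07, and adjusted p = 0.15 with an estimated correlation). Glycolysis had 0.31 (0 of 17; 2 adjusted over the list alone, adjusted p = 0.0012, and adjusted p = 0.27 with an estimated correlation) and fatty acid use 0.29 (0 of 18; 0 adjusted over the list alone, adjusted p = 0.0028, and adjusted p = 0.29 with an estimated correlation). Macrophage markers had -0.25 (0 of 20; 0 adjusted over the list alone, adjusted p = 0.04, and adjusted p = 0.31 with an estimated correlation). In the denervation list, which did not pass, Eif4ebp1 had 0.66 (adjusted p = 0.041, and adjusted p = 0.31 at highest, without diaphragm wild type 10 months replicate 2). The adipocyte list had a median of -0.09 with a test pointing up and the immediate early list 0.05 with a mean of -0.01 and a test pointing down.

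Genes that hepatocytes express fell in the diaphragm. Hpx and Ambp, for the plasma proteins hemopexin and bikunin, Fabp1, for the liver fatty acid carrier, and Apoa1, for the main protein of high-density lipoprotein, had changes of -3.49 ± 0.75 (adjusted p = 0.0074), -3.47 ± 0.69 (adjusted p = 0.0044), -3.36 ± 0.58 (adjusted p = 0.0018) and -3.14 ± 0.58 (adjusted p = 0.0028). Hpx reached adjusted p = 0.099 without diaphragm transgenic 7 months replicate 1 and Ambp adjusted p = 0.053 without wild type 10 months replicate 2. On this list, added after its genes were seen among the falls, 17 of 21 fell (20 adjusted over the list alone, median -2.81). Averaged over the muscles 0 of 21 passed (13 fell adjusted over the list alone, median -0.66). The mean log2 signal of the list was 12.08 ± 1.06 in wild-type and 9.52 ± 1.94 in transgenic diaphragm (mean ± SD, n = 4 each), and between 6.53 and 7.36 on the limb arrays. It was 12.29 on the transgenic 7 months replicate 2 array, within the wild-type range of 10.54 to 12.97. With this mean as a covariate in the diaphragm 1 probe set passed, that of Ankrd2.

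**Figure D3:**
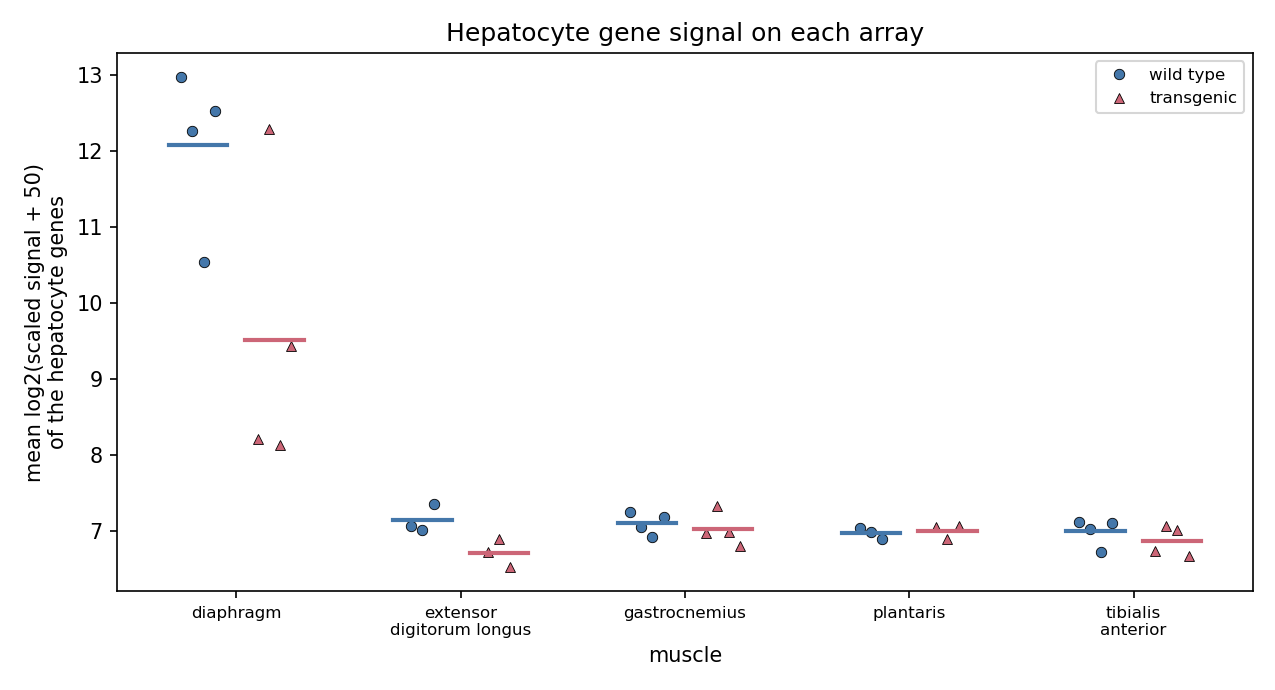
Mean log2(signal + 50) of the hepatocyte genes on each array, by muscle and genotype, with bars at the means. The diaphragm means were 12.08 in wild type and 9.52 in transgenic arrays.

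In tibialis anterior, a muscle made almost wholly of fast fibres, the largest rises were slow fibre genes. Myh7 and Myl2 encode the slow myosin heavy and light chains, and Tnnc1 and Tnnt1 slow troponin C and T. Tnni1 and Atp2a2 rose with them, as did Ankrd2 and Csrp3. Cyfip2, a regulator of actin branching, fell. Myh7 changed by 3.24 ± 0.37 (signal 390 ± 285 to 3700 ± 1360, mean ± SD, n = 4 each; adjusted p = 5.5e-06), and Myl2 by 3.21 ± 0.25 (569 ± 235 to 5470 ± 1440; adjusted p = 3.5e-09). Ankrd2 changed by 2.97 ± 0.28 (1060 ± 297 to 8550 ± 1830; adjusted p = 1.6e-07), Tnnc1 by 2.75 ± 0.49 (164 ± 181 to 1120 ± 522; adjusted p = 0.0077), Tnnt1 by 2.54 ± 0.26 (580 ± 140 to 3680 ± 1210; adjusted p = 7.1e-07) and Csrp3 by 2.22 ± 0.35 (adjusted p = 0.0014). Tnni1 rose by 1.57 (adjusted p = 0.0041) and Atp2a2 by 1.54 (adjusted p = 0.0061), 2 genes chosen here after their values were seen. Cyfip2 had -1.07 ± 0.21 (adjusted p = 0.022). Myh7, Myl2, Ankrd2, Tnnc1, Tnnt1, Csrp3 and Cyfip2 were named among genes without overlap between genotypes. By that rule each of the 4 transgenic arrays lay beyond each wild-type array. Second probe sets had -0.11 for Myh7 and 0.31 for Tnnt1. Tpm3 had 0.82 ± 0.37 (1480 ± 611 to 2620 ± 1110; adjusted p = 0.78), with 1.40 in the filled-record and 0.23 in the empty-record arrays, Tpm1 -0.27 (adjusted p = 0.83), Tpm2 0.12 (adjusted p = 0.91) and Tpm4 -0.20 (adjusted p = 0.86).

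**Figure D4:**
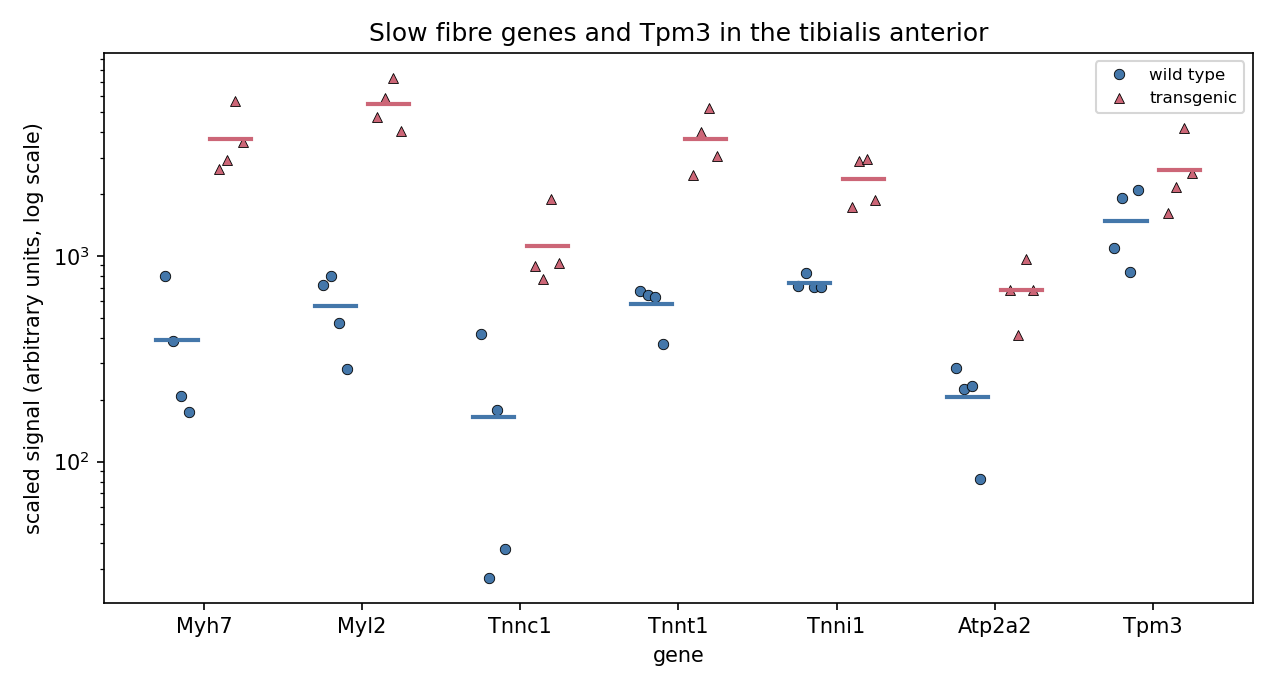
Scaled signal of 7 slow fibre genes on the tibialis anterior arrays, with bars at the means. Myh7 had a log2 change of 3.24 and Tpm3 of 0.82.

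In tibialis anterior 14 probe sets passed (13 higher and 1 lower; 592 at unadjusted p under 0.05), and 27 (25 higher and 2 lower) with the set of arrays as a block. With scan day as a block 44 passed, and with the tibialis anterior arrays fitted alone 4. Within the filled-record arrays 4 passed and within the empty-record arrays 5, with Myh7 at 3.07 and 3.40 and Myl2 at 3.22 and 3.20. The count was 7 without tibialis anterior wild type 7 months replicate 2, 8 without wild type 10 months replicate 2, and 9 without either transgenic 7 months replicate 2 or transgenic 10 months replicate 1. Tnnc1 lost the threshold without 3 single arrays, with a highest adjusted p = 0.086 without wild type 7 months replicate 2, and Cyfip2 without 5, with a highest adjusted p = 0.2 without transgenic 7 months replicate 2. Myh7, Myl2, Ankrd2, Tnnt1 and Csrp3 kept the threshold. Of 10 slow fibre genes 6 rose (7 adjusted over the list alone, median 1.56, 1.54 in the filled-record and 1.58 in the empty-record arrays; adjusted p = 1.9e-24). With an estimated correlation the adjusted p = 1e-04, and with the block added the adjusted p = 0.0011. The Z-disc list had a median of 0.13 (2 of 17 rose, Ankrd2 and Csrp3; 3 adjusted over the list alone, adjusted p = 8.5e-05). With an estimated correlation its adjusted p = 0.045, and with the block added adjusted p = 0.17. Heat shock genes (0 of 19; 1 adjusted over the list alone, median 0.31, adjusted p = 8.5e-05) had adjusted p = 0.25 with an estimated correlation. Proteasome genes (0 of 28; 0 adjusted over the list alone, median 0.22, adjusted p = 9.1e-05) had adjusted p = 0.41 with an estimated correlation. Fast fibre genes (0 of 12; 0 adjusted over the list alone, median -0.25, adjusted p = 0.0017) had adjusted p = 0.47 with an estimated correlation. The denervation and endothelial lists had medians of -0.13 and -0.06 with tests pointing up.

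In extensor digitorum longus the gene that passed was Ankrd2, the stretch-responsive ankyrin repeat protein. It changed by 2.47 ± 0.32 (signal 1040 ± 94.2 to 6240 ± 2130, mean ± SD, n = 3 each; adjusted p = 0.00027), and its highest adjusted p without 1 array was 0.0089. Csrp3 had 1.88 (adjusted p = 0.16). Tpm2 had 0.33 (adjusted p = 0.84), Tpm3 0.29 (adjusted p = 0.96), Tpm1 -0.09 (adjusted p = 0.98) and Tpm4 0.08 (adjusted p = 0.98). The count was 1 of 9322 (601 at unadjusted p under 0.05), 2 with the set of arrays as a block, 5 within the filled-record arrays and 0 within the empty-record arrays (limma; 128 at unadjusted p under 0.05). The slow fibre list had a median of 0.29 (0 of 10; 0 adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.25 with an estimated correlation). The Z-disc list had 0.04 (1 of 17 rose; 3 adjusted over the list alone, adjusted p = 0.004, and adjusted p = 0.25 with an estimated correlation). Extracellular matrix genes had 0.13 (0 of 22; 0 adjusted over the list alone, adjusted p = 0.04, and adjusted p = 0.25 with an estimated correlation). Fast fibre genes had -0.24 (0 of 12; 1 fell adjusted over the list alone, adjusted p = 0.0037, and adjusted p = 0.47 with an estimated correlation). Heat shock genes had 0.21 (0 of 19; 1 adjusted over the list alone, adjusted p = 0.0036, and adjusted p = 0.43 with an estimated correlation) and proteasome genes 0.20 (0 of 28; 0 adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.43 with an estimated correlation). The denervation and immediate early lists had medians of -0.02 and -0.04 with tests pointing up, and the clock list 0.05 with a mean of -0.05 and a test pointing down.

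In gastrocnemius Ankrd2 and Csrp3 had positive values that did not pass. Ankrd2, with 1.39 ± 0.28 (signal 1690 ± 588 to 4330 ± 659, mean ± SD, n = 4 each), had adjusted p = 0.29, and Csrp3, with 1.16, had adjusted p = 1. Tpm1 had -0.33, Tpm2 0.20, Tpm3 0.03 ± 0.37 and Tpm4 -0.08 (adjusted p = 1 for each). The count was 0 of 9322 (limma; 209 at unadjusted p under 0.05). It was also 0 with the block (408), within the filled-record (233) and empty-record arrays (379), and with scan day as a block (661), with the counts at unadjusted p under 0.05 in brackets. The myogenic list, with regulators of muscle differentiation, had a median of 0.15 (0 of 20; 0 adjusted over the list alone, adjusted p = 0.016, and adjusted p = 0.39 with an estimated correlation). Heat shock genes had 0.16 (0 of 19; 1 adjusted over the list alone, adjusted p = 0.012, and adjusted p = 0.78 with an estimated correlation) and proteasome genes 0.10 (0 of 28; 0 adjusted over the list alone, adjusted p = 0.012, and adjusted p = 0.82 with an estimated correlation). Fast fibre genes had -0.11 (0 of 12; 0 adjusted over the list alone, adjusted p = 0.047, and adjusted p = 0.82 with an estimated correlation). The adipocyte list had a median of 0.04 with a mean of -0.01, and the clock list 0.04 with a mean of -0.02 and a test pointing down.

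In plantaris the extracellular matrix list, with the collagens and their partners, shifted up, although no single member passed. Its median was 0.27 (0 of 22; 0 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.025 with an estimated correlation). With the block added the adjusted p = 0.08, and the medians were 0.29 in the filled-record (adjusted p = 0.0054) and 0.17 in the empty-record arrays (adjusted p = 0.1). Its highest-signal members were Dcn, a collagen-binding proteoglycan (-0.25), and Col1a1, for a fibrillar collagen (0.19). Ankrd2 had 1.77 ± 0.32 (signal 3260 ± 1520 to 10700 ± 3250, mean ± SD, n = 3 each), with adjusted p = 0.073, and adjusted p = 0.022 with the block. Csrp3 had 1.37 (adjusted p = 1). Tpm1 had 0.18, Tpm2 0.05, Tpm3 0.26 and Tpm4 -0.15 (adjusted p = 1 for each). The count was 0 of 9322 (limma; 174 at unadjusted p under 0.05). It was 1 with the set of arrays as a block and 0 within the filled-record (287) and empty-record arrays (107), with the counts at unadjusted p under 0.05 in brackets. The count was 1 without each of extensor digitorum longus wild type and transgenic 10 months, gastrocnemius wild type 7 months replicates 1 and 2, plantaris wild type 7 months replicate 2 and tibialis anterior wild type 10 months replicate 2. Another 7 lists passed with the preset correlation, each with adjusted p = 0.4 with an estimated correlation and 0 members past the threshold. These were slow fibre (median 0.30, adjusted p = 0.018), Z-disc (0.18, adjusted p = 0.015; 2 rose adjusted over the list alone), heat shock (0.19, adjusted p = 0.015), nerve and Schwann cell (0.25, adjusted p = 0.049), fast fibre (-0.21, adjusted p = 0.0033), oxidative phosphorylation (-0.13, adjusted p = 0.014) and glycolysis (-0.20, adjusted p = 0.015). In all of these but the Z-disc list 0 were past adjusted over the list alone. The denervation list had a median of 0.09 with a mean of -0.05 and a test pointing down.

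Between muscles, the genotype effect differed for 1 probe set each of 3 slow fibre genes, Myl2, Tnnt1 and Myh7, which encode parts of the slow myosin and troponin. Tnnt1 and Myh7 each had a second probe set, which did not pass. Myl2 had log2 changes of 0.53, 0.76, 0.03, 0.01 and 3.21 in diaphragm, extensor digitorum longus, gastrocnemius, plantaris and tibialis anterior (moderated F test, adjusted p = 2.8e-05). Tnnt1 had 0.38, 0.29, 0.06, 0.07 and 2.54 (adjusted p = 0.0037) and Myh7 0.46, 0.30, 0.07, 0.26 and 3.24 (adjusted p = 0.021). The wild-type signal of Myl2 was 569 in tibialis anterior against 9930 to 22100 in the other muscles, that of Tnnt1 580 against 14100 to 33300 and that of Myh7 390 against 9190 to 22400. These were the 3 of 9322 probe sets that passed (374 at unadjusted p under 0.05). The count was 6 within the filled-record arrays and 0 within the empty-record arrays (limma; 106 at unadjusted p under 0.05), and 121 without diaphragm transgenic 7 months replicate 2. Myh7 reached adjusted p = 0.19 without tibialis anterior transgenic 10 months replicate 1 and lost the threshold without 5 single arrays in all.

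Between the diaphragm and the mean of the 4 limb muscles, the genotype effect was larger for Padi2, Sh3bgr, a small muscle protein, and Psmb1, and more negative for hepatocyte genes such as Hamp, the iron hormone, and Serpinc1, antithrombin. Padi2 had a difference of 1.25 ± 0.28 (adjusted p = 0.042), Sh3bgr 1.12 ± 0.19 (adjusted p = 0.018) and Psmb1 1.02 ± 0.22 (adjusted p = 0.04). Ankrd28, a phosphatase subunit (0.92), Prpf19, a splicing factor (0.81), and Nfe2l1, which induces proteasome genes (0.72), had adjusted p = 0.048 each. Hamp had -4.16 ± 0.73 (adjusted p = 0.024), Hpx -3.52 (adjusted p = 0.048), Ambp -3.44 (adjusted p = 0.043), Fabp1 -3.37 (adjusted p = 0.036), Mup3, a urinary protein, -3.29 (adjusted p = 0.048) and Serpinc1 -3.28 (adjusted p = 0.042). Tpm2 had 0.52 (adjusted p = 0.3), Tpm3 0.07, Tpm1 -0.11 and Tpm4 0.03 (adjusted p = 1 for the last 3). In all 76 probe sets passed (9 higher and 67 lower; 745 at unadjusted p under 0.05). There were 154 (35 higher and 119 lower) with the set of arrays as a block, 139 within the filled-record arrays and 0 within the empty-record arrays (limma; 166 at unadjusted p under 0.05). With scan day as a block, with 20 group means and with the hepatocyte covariate there were 0 (limma; 587, 648 and 236 at unadjusted p under 0.05), and with a pseudocount of 16 there was 1. Whichever 1 of the 36 arrays was left out the count moved, from 0, for instance without diaphragm wild type 7 months replicate 1, to 238 without diaphragm transgenic 7 months replicate 2, and each of these 12 genes lost the threshold. Sh3bgr reached adjusted p = 0.16 without diaphragm wild type 7 months replicate 1, and Hamp and Fabp1 0.22 without diaphragm wild type 10 months replicate 2. The other 9 reached 0.25 to 0.34 without diaphragm transgenic 7 months replicate 1.

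On the hepatocyte list 11 of 21 fell (18 adjusted over the list alone, median -2.45). With the preset correlation 7 lists shifted up in the diaphragm relative to the limb muscles, and none did with an estimated correlation. Fast fibre genes had a median difference of 0.66 (1 of 12 rose, Myoz1, at 0.70 with adjusted p = 0.049; 8 adjusted over the list alone, adjusted p = 5.3e-11, and adjusted p = 0.068 with an estimated correlation). Z-disc genes had 0.59 (0 of 17; 1 adjusted over the list alone, adjusted p = 8.7e-06, and adjusted p = 0.05 with an estimated correlation). Oxidative phosphorylation (0.33; 0 of 40; 1 adjusted over the list alone, adjusted p = 7e-09), glycolysis (0.46; 0 of 17; 5 adjusted over the list alone, adjusted p = 6.9e-07) and proteasome genes (0.38; 1 of 28 rose; 2 adjusted over the list alone, adjusted p = 7.2e-09) each had adjusted p = 0.072 with an estimated correlation. Myogenic regulators had 0.19 (0 of 20; 2 adjusted over the list alone, adjusted p = 0.03, and adjusted p = 0.15 with an estimated correlation) and fatty acid genes 0.24 (0 of 18; 0 adjusted over the list alone, adjusted p = 0.03, and adjusted p = 0.47 with an estimated correlation). The lymphocyte list had a median of -0.10 with a mean of 0.10 and a test pointing up. The endothelial, nerve and cell cycle lists had medians of 0.02, 0.03 and 0.03 with tests pointing down.

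Among wild-type muscles the genes that differed with the smallest p were slow fibre genes (Tnnt1, Myl2, Atp2a2, Myh7, Tnni1), the fast fibre genes Actn3 and Myoz1, which encode Z-disc proteins, Sh3bgr, and the hepatocyte genes Apoa1 and Ahsg. The wild-type diaphragm carried less of the fast fibre and glycolysis genes than the limb muscles and more of the macrophage markers, which phagocytes express. It also carried hepatocyte genes at far higher signal. How much of the other differences follows from hepatocyte RNA on the diaphragm arrays was not tested. Tnnt1 had adjusted p = 4.5e-12 in the F test over the 5 muscles, Myl2 7.9e-12, Actn3 5.1e-10, Atp2a2 8.4e-10, Apoa1 2.4e-09, Myh7 3.1e-09, Sh3bgr 3.5e-09, Tnni1 5.4e-09, Myoz1 6.7e-09 and Ahsg 7.4e-09. In all 1064 of 9322 passed at the 7-month level (1965 at unadjusted p under 0.05), and 1411 with the ages weighted equally. There were 1602 with the set of arrays as a block, 645 within the filled-record arrays, 150 within the empty-record arrays and 570 without diaphragm wild type 7 months replicate 1. Between the 4 limb muscles alone 37 passed (73 with the block).

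For the wild-type diaphragm minus the mean of the 4 limb muscles, at the 7-month level, Apoa1 had a log2 difference of 8.18 ± 0.56 (adjusted p = 7.1e-11), Fabp1 7.51, Ahsg 7.35, Alb, serum albumin, 7.29, Hpx 7.21 and Ambp 7.12. With the ages weighted equally these were 7.56, 6.77, 6.45, 7.64, 6.46 and 6.25. On limb arrays such genes lie near background (Apoa1 at 26.21 to 153.6 on the wild-type arrays), so the sizes depend on the pseudocount (Apoa1 8.86 with 16 and 6.79 with 200). The largest negative differences were Actn3 (-3.45 ± 0.22, adjusted p = 1.7e-11), Cd24a, a surface glycoprotein (-2.80), Smyd2, a methyltransferase (-2.78), Myh4, the fastest myosin (-2.56; -0.03 on a second probe set), Tspan8, a tetraspanin (-2.35), and Sh3bgr (-2.26). Tpm2 had -0.63 ± 0.16 (adjusted p = 0.0056, and adjusted p = 0.13 without diaphragm wild type 7 months replicate 1). Tpm4 had 0.54 (adjusted p = 0.054, and adjusted p = 0.029 with the block), Tpm3 0.59 (adjusted p = 0.32) and Tpm1 0.32 (adjusted p = 0.29). With the ages weighted equally Tpm4 and Tpm1 had adjusted p = 0.00544 and adjusted p = 0.0483. In all 1619 passed (791 higher and 828 lower; 2576 at unadjusted p under 0.05). Within the empty-record arrays 453 passed, and without diaphragm wild type 7 months replicate 1 there were 900. All 12 fast fibre genes were lower (12 adjusted over the list alone, median -1.16, adjusted p = 4.8e-13; adjusted p = 0.03 with an estimated correlation, and adjusted p = 0.059 with the block added). Of 17 glycolysis genes 13 were lower (14 adjusted over the list alone, median -1.28, adjusted p = 1.3e-12; adjusted p = 0.03 with an estimated correlation, and adjusted p = 0.05 with the block added), among them Phkg1, a phosphorylase kinase subunit (-2.20), and the enzymes Eno3 and Ldha (-1.47 each). Of 20 macrophage markers 11 were higher (11 adjusted over the list alone, median 0.78, adjusted p = 2.5e-06; adjusted p = 0.03 with an estimated correlation, and adjusted p = 0.05 with the block added), among them the chemokine Ccl9 (2.31), the lysozyme Lyz2 (1.65) and the complement gene C1qa (1.64). On the hepatocyte list 20 of 21 were higher (20 adjusted over the list alone, median 5.90).

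The other lists that passed in this comparison did so with the preset correlation only. Slow fibre genes (4 higher and 1 lower of 10; 5 and 1 adjusted over the list alone, median 0.84, adjusted p = 0.046) had adjusted p = 0.41 with an estimated correlation, with Atp2a2 at 1.09 and Myl2 and Tnnt1 at 0.96 each. Without diaphragm wild type 7 months replicate 2 Myl2 reached adjusted p = 0.2 and Tnnt1 adjusted p = 0.16. Myogenic regulators (7 of 20 lower; 9 lower and 1 higher adjusted over the list alone, median -0.61, adjusted p = 0.003) had adjusted p = 0.063 with an estimated correlation. Z-disc genes (7 of 17 lower; 10 adjusted over the list alone, median -0.79, adjusted p = 0.0018) and proteasome genes (17 of 28 lower; 20 adjusted over the list alone, median -0.71, adjusted p = 8.9e-09) had adjusted p = 0.068 with an estimated correlation. Adipocyte markers (5 higher and 1 lower of 10; 7 and 1 adjusted over the list alone, median 0.83, adjusted p = 0.0058) had adjusted p = 0.2 with an estimated correlation. Oxidative phosphorylation (1 higher and 10 lower of 40; 1 and 14 adjusted over the list alone, median -0.40, adjusted p = 0.00016) had adjusted p = 0.26, and fatty acid genes (5 higher and 1 lower of 18; 6 and 2 adjusted over the list alone, median 0.29, adjusted p = 0.026) had adjusted p = 0.41, both with an estimated correlation. The cell cycle list had a median of -0.06 and the extracellular matrix list -0.04 with tests pointing up, and the immediate early list 0.07 with a mean of -0.01.

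With age, from 7 to 10 months, no gene passed in either genotype, and Tpm3 had -0.09 ± 0.27 in wild type and 0.46 ± 0.27 in transgenic muscle (adjusted p = 1 for both; interaction 0.55 ± 0.39, adjusted p = 1). Tpm1 had 0.30 and 0.08, Tpm2 0.05 and 0.07, and Tpm4 0.31 and 0.16 (adjusted p = 1 for each). In the interaction Tpm1 had -0.22, Tpm2 0.01 and Tpm4 -0.14 (adjusted p = 1 for each). Slow fibre genes had a median change with age of 0.20 in transgenic muscle (0 of 10; 0 adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.67 with an estimated correlation). In the interaction slow fibre genes had 0.40 (0 of 10; 0 adjusted over the list alone, adjusted p = 0.0071) and fast fibre genes, of the quickest contracting fibres, 0.20 (0 of 12; 0 adjusted over the list alone, adjusted p = 0.0067), each with adjusted p = 0.65 with an estimated correlation. In wild type no list passed, the lowest adjusted p being 0.41. The counts were 0 for age in wild type, age in transgenic muscle and the interaction (limma; 401, 406 and 195 at unadjusted p under 0.05). They were 0 with the set of arrays as a block (707, 693 and 353 at unadjusted p under 0.05). At 10 months the wild-type and transgenic arrays of diaphragm, gastrocnemius, plantaris and tibialis anterior with a recorded scan day were scanned on different days, so the interaction cannot be separated from the scan day. Several lists had medians and tests of opposite sign. For age in wild type these were the endothelial list (-0.01, test up) and the nerve, fatty acid and cell cycle lists (0.09, 0.03 and 0.08, tests down). The immediate early list had -0.03 with a mean of 0.03. In transgenic muscle it was the adipocyte list (0.01, mean -0.02), and in the interaction the denervation and Z-disc lists (0.02 each, tests down) and the extracellular matrix list (0.02, mean -0.02).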

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

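The tests of single arrays and of differences between muscles in this part were fixed before the results were seen. The comparisons with the hepatocyte signal and its covariate were chosen afterwards. A gene signal or array measure was tested in 80 cases, each on the 4 arrays of 1 muscle and genotype at both ages. In 9 of them 1 array stood apart from the other 3 by more than Dixon's 95% value. Chance gives about 1 in 20 for a single test. The same groups of arrays recur over many measures, so the tests are not independent and the 9 cannot be set against that rate.

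Diaphragm wild type 10 months replicate 1 had the highest signal of its group for Tpm4 (3040 against 1760 to 1890) and for Hoxa7 (84.9 against 33.6 to 36.3). Diaphragm wild type 7 months replicate 1 had the highest for Ptprd (1150 against 413 to 442). Among the transgenic diaphragm arrays, 10 months replicate 2 stood apart for Tpm3 (30600 against 13600 to 16400) and 10 months replicate 1 for Hoxa7 (335 against 255 to 257). In tibialis anterior, wild type 10 months replicate 1 stood apart for Tpm2 (17700 against 13600 to 14200), and wild type 10 months replicate 2 had the lowest Tnnt1 (371 against 634 to 674). Transgenic 10 months replicate 1 had the highest Tnnc1 (1900 against 769 to 919) and the highest percentage of probe sets at a signal of 100 or more (64.4 against 60.2 to 60.5). Hoxa7 stayed past the threshold in the diaphragm without any 1 array (highest adjusted p = 0.048), and Ptprd and Tnnc1 did not (highest adjusted p = 0.36 without diaphragm wild type 7 months replicate 1, and adjusted p = 0.086 without tibialis anterior wild type 7 months replicate 2).

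The genotype effect differed between muscles for 3 probe sets in the test of the difference itself, those of Myl2 (adjusted p = 2.8e-05), Tnnt1 (adjusted p = 0.0037) and Myh7 (adjusted p = 0.021). Each had its largest log2 change in tibialis anterior (3.21, 2.54 and 3.24). In 91 splits of the arrays within muscles 2 called at least 3 probe sets, the real one included. The highest other count was 218, many times the real one, which points to a structure of the samples. A relabelling can thus call far more than 3, so the splits do not exclude chance for this count. In that split the sides of the diaphragm arrays differed by 3.44 in mean hepatocyte log2 signal, against 2.56 between the genotypes.

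The genotype effect differed between the diaphragm and the limb muscles for 76 probe sets. In 91 splits 9 called at least as many, the real one included, and the highest other count was 487, in a split whose diaphragm sides again differed by 3.44 in hepatocyte signal. Chance is not excluded for this count, and with the hepatocyte covariate 0 probe sets passed (limma; 236 at unadjusted p under 0.05).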

How the results depend on the processing

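Alternatives with the hepatocyte covariate, the ages weighted equally for wild-type muscles, the 4 limb muscles alone, the 2 arrays with a Gapdh ratio over 3 left out, the array whose record names plantaris left out, and the list tests with the block or covariate added were chosen after the data were seen; the others were planned. The cause of the changes below was not tested except where a paragraph names one. Age effects could not be estimated with scan day as a block.

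With the replicate number as a block, which follows the set of arrays and was checked as a pairing, the counts were 536 in diaphragm (319 without it), 2 in extensor digitorum longus (1), 1 in plantaris (0), 27 in tibialis anterior (14), 594 in the average (109), 154 for diaphragm against limb muscles (76) and 1602 for wild-type muscles (1064). With scan day as a block they were 146 in diaphragm (102 shared), 4 in extensor digitorum longus, 44 in tibialis anterior, 973 in the average (100 shared) and 0 for diaphragm against limb muscles (limma; 587 at unadjusted p under 0.05). A random block for shared pools gave 20 in the average (19 higher and 1 lower), 200 for diaphragm against limb muscles and 1695 for wild-type muscles.

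The filled-record arrays alone gave 5 in extensor digitorum longus, 4 in tibialis anterior, 56 in the average, 6 for the difference between muscles, 139 for diaphragm against limb muscles and 645 for wild-type muscles. The empty-record arrays alone gave 0 in diaphragm (limma; 479 at unadjusted p under 0.05), 0 in extensor digitorum longus (128), 5 in tibialis anterior, 2 in the average (1209), 0 for the difference between muscles (106), 0 for diaphragm against limb muscles (166), 150 for wild-type muscles and 453 for the wild-type diaphragm against limb muscles (1619 on all arrays). These sets hold fewer arrays.

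Array weights gave 633 in diaphragm, 2 in plantaris, 444 in the average, 78 for the difference between muscles and 263 for diaphragm against limb muscles. Each muscle alone gave 2 in diaphragm (both higher) and 4 in tibialis anterior. A model of 20 means gave 204 in diaphragm, 3 in extensor digitorum longus, 67 in the average and 0 for diaphragm against limb muscles (limma; 648 at unadjusted p under 0.05). Quantile normalization gave 1 in plantaris and 117 for diaphragm against limb muscles, and in the average 86.3% of 102 were higher, against 73.4% of 109. One probe set per gene gave 1 in plantaris. For diaphragm against limb muscles a pseudocount of 16 gave 1, one of 200 gave 158, and the deposited values with no rescaling, where the pseudocount of 50 is smaller beside the signal, gave 4 (3 shared). No filter gave 2 for age in wild type (0).

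With the hepatocyte covariate the counts were 1 in diaphragm, 48 in the average and 0 for diaphragm against limb muscles (limma; 236 at unadjusted p under 0.05), and with the block added 1, 298 and 0 (265). The change of sign follows from removing the hepatocyte signal itself. In the diaphragm Hpx went from -3.49 to 0.32 (0.39 with the block) and Ambp from -3.47 to 0.18 (0.19). For diaphragm against limb muscles Hpx went from -3.52 to 0.28 (0.35), Ambp from -3.44 to 0.21 (0.23) and Serpinc1 from -3.28 to 0.18 (0.14). The 4 limb muscles alone gave 37 in the average and 37 for wild-type muscles (73 with the block). Without the 2 arrays with a Gapdh ratio over 3 there were 1 in plantaris, 67 in the average and 1 for diaphragm against limb muscles. Without the array whose record names plantaris the last was 27.

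Of the 39 list shifts over the 6 genotype comparisons, 8 passed with an estimated correlation, 14 with fry, 4 with the block and an estimated correlation, and 9 with the hepatocyte covariate and an estimated correlation.

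Leaving out each array in turn gave 65 to 429 in diaphragm, 0 to 1 in plantaris, 7 to 18 in tibialis anterior, 66 to 269 in the average, 2 to 121 for the difference between muscles, 0 to 238 for diaphragm against limb muscles, 570 to 1107 for wild-type muscles and 900 to 1708 for the wild-type diaphragm against limb muscles. The lone remaining array of a group is then assumed to vary like the others. Extensor digitorum longus stayed at 1, and gastrocnemius, age and the interaction at 0. For named genes under the other settings, 2876 comparisons kept their side of the threshold, 544 became weaker, 11 stronger and 10 reversed, the ones above, and 33 that had not passed changed sign. Leaving out arrays gave 6410, 745, 11, 0 and 38, and for single lists the numbers were 931, 183, 22, 0 and 64, the last for tests that changed direction without passing both ways.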

Other observations

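In this part all comparisons with the hepatocyte covariate, those of the lists and of the rises and falls, and the tests of the slow fibre list in the 2 sets of arrays, of the slow fibre list with an estimated correlation, of the falls in transgenic arrays and of the splits with the block were chosen after the results were seen. The hepatocyte list itself was added after the data were seen, and the other tests were set before their results were seen.

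Diaphragm arrays carried hepatocyte RNA, less of it on 3 of the 4 transgenic arrays, and a candidate explanation is that unequal amounts of liver tissue came with the diaphragm samples. Over the 8 diaphragm arrays 18 of 21 hepatocyte genes kept a slope between 0.7 and 1.3 on the mean of the others (median 1.09), which is what unequal liver tissue predicts, and 125 of the 208 falls were over 1 log2 unit higher in transgenic diaphragm than in transgenic limb muscles (60.1%, against 3.5% of all probe sets), although they were chosen as low on these diaphragm arrays. Against the muscle lists' median change of 0.35, 12 rises stayed past the threshold. These were Ankrd2, Csrp3, Xirp1, Nrap, Padi2, Hoxa7, Psmb1, Bag3, Amot, Sh3bgr, Prpf19 and Nfe2l1. That median is over 79 slow fibre, fast fibre, glycolysis and oxidative phosphorylation genes. Liver RNA need not dilute all genes alike, so the median may understate the dilution of some rises. With the hepatocyte covariate only Ankrd2 kept the threshold. Less dilution of muscle RNA by liver RNA is thus not the whole cause for Ankrd2 (3.01), and it stays open for the others of these. The Z-disc list's shift kept adjusted p = 0.002 with the covariate and an estimated correlation (camera). The covariate is linear in the mean log2 hepatocyte signal and need not remove all dilution, so less dilution is not excluded for that shift. The proteasome list's shift may come from less dilution, as its median went from 0.51 to 0.22 and its adjusted p to 0.26, and for the other rises it stays open. With the covariate the rises went from a median of 0.90 (SE 0.20) to 0.64 (SE 0.30) and the falls from -2.11 to -0.17, so the calls ended for the rises with a smaller value and a wider error together, and for the falls mainly with the smaller value; whether the genotype changes the diaphragm's contact with the liver was not tested.

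The slow fibre genes rose in tibialis anterior, and 3 explanations were weighed. The set of arrays was balanced over genotype in this muscle, so by design it could not give the rise by itself. The list's median change was 1.54 in one set and 1.58 in the other. On the filled-record arrays wild type and transgenic were scanned on different days, and scan day was not weighed here. Slow muscle tissue carried over into the transgenic samples and more slow fibres or slow gene expression in the muscle itself cannot be told apart. For the first, the highest share of the gastrocnemius excess gained by a slow gene was 3.26 times the lowest (SE 1.84, allowed 3; Myl2 25.1% and Tpm3 7.7%), an allowance for the error that was added after the value was seen, and the gastrocnemius profile is itself an assumption. For the second the list's adjusted p = 1e-04 with an estimated correlation, which both explanations predict, and a shift of fibre type with the transgene may be one reading of it.

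A gastrocnemius array (transgenic 7 months replicate 1) has a record that names plantaris. On 100 genes for each muscle that part gastrocnemius from plantaris its score was 0.88, where the other gastrocnemius arrays had 0.72 to 1.05 and the plantaris arrays -0.13 to 0.25, so plantaris RNA on it is excluded. Another record, of gastrocnemius wild type 7 months replicate 1, gives an age of 6 months and female sex. Xist signal lay between 76 and 861 on all arrays and the highest Y-linked signal between 7 and 119.

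Other splits of the arrays into groups of the same sizes showed which counts chance can give. For the average 1 of 91 splits reached 109, the real one (highest other 2), and for tibialis anterior 1 of 34 reached 14 (highest other 3). For wild-type muscles 1 of 100 reached 1064 (highest other 1010, in a split that kept all 4 diaphragm arrays under 1 label). No other split reached these counts in the model without the block, and their splits were not counted with it. The splits for the average relabelled each muscle separately, so they do not cover pools of mice shared between muscles. With a random block for such pools the average called 20. For tibialis anterior 1 of 34 is the smallest share that the splits can give, and several results were tested in this way. For the diaphragm 2 of 34 reached 319 and the highest other was 476, so chance is not excluded. With the block 1 of 34 reached 536, but the same parting of the hepatocyte signal (3.44 between the sides) gave the highest other at 535, so this count leaves it open. The split with 476 put the arrays with a hepatocyte mean of 12.27 to 12.97 on one side and those with 8.13 to 10.54 on the other. For extensor digitorum longus (1, highest other 0; 1 of 10 splits) and plantaris (0, highest other 0; 10 of 10) the splits are too few. For gastrocnemius 34 of 34 reached 0 (highest other 3), and for age in wild type, age in transgenic muscle and the interaction 100 of 100 reached 0 (highest others 544, 1 and 1). Every split reaches a count of 0, so these 4 say nothing about chance. The split with 544 had 2 of 8 arrays of replicate number 1 on its older side against 5 of 8 in the real one. With the set of arrays as a block that split called 1, so most of its calls went with the set, and the highest of the drawn splits called 18. The real count for age in wild type with the block was 0 (limma; 707 at unadjusted p under 0.05).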
